A study of Arabidopsis thaliana with 12 samples.

How the data were processed

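RNA from rosette leaves of 31-day-old Arabidopsis thaliana plants (Columbia) was measured on 12 one-colour oligonucleotide arrays, 3 for each of 4 groups: wild type watered, wild type under drought, ahp2,3,5 watered and ahp2,3,5 under drought. Per the labels, plants grew for 2 weeks on plates and 1 week in soil at 22 °C, with 16 h of light (60 µmol per m2 and s) and 8 h of darkness, and were then left without water for 10 days or watered in parallel. Per the labels, 0.5 µg of RNA was labelled with Cy3. The genotype labels read ahp2,3,5, while the growth text once writes ahk2,3,5; the array signals of AHP2, AHP3 and AHP5 are given with the results. The design text speaks of 3 hybridizations per biological sample, so the p-values may measure technical spread alone, and the number of arrays limits the precision of every value.

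Scanner tables and a value table were deposited, and both were read. Per the file headers, the scanner tables hold the intensity of each spot from Agilent Feature Extraction, as a background-subtracted and detrended processed signal, next to raw spot and local background intensity and flags for each spot. The deposited value table of the authors holds log2 values. Tested on the values, each of its columns correlated with the log2 processed signal of the same array at r = 1. Its medians run from -3.60 to -2.85, close to the -3.61 to -2.86 found here after subtracting the 75th percentile of the array. The columns thus hold that signal minus a value close to this percentile, with no centring of genes.

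Each array held 43803 spots other than controls. Of these, 66.5 to 73.7% were well above background, 99 to 395 were outliers and were left out, and 0 were saturated. After spots of one probe were averaged, 43603 probes remained. A locus could be assigned to 39057 of them from the annotation in the files, 38413 by transcript code and 644 by gene name, while 4546 carried none. Accessions in the reference gene table assigned 0 more. These probes covered 29043 loci, of which 28608 were found in the reference gene table, built on TAIR10.1, which gave most symbols, and the gene name in the files served elsewhere. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Where a locus had more than 1 probe (7744 loci), the probe with the highest mean signal was used.

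Signals were log2 transformed and scaled by subtracting the 75th percentile of the array. A gene was tested if its probe was well above background on all 3 arrays of at least 1 group and had at least 2 values in each group, which left 21255 genes. One linear model with a mean for each of the 4 groups was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes; 8 residual degrees of freedom and a prior of 1.98). There were 5 comparisons: drought against watered in the wild type, drought against watered in the mutant, mutant against wild type when watered, mutant against wild type under drought, and the difference of the 2 drought responses (response in the mutant minus response in the wild type). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Log2 differences are given with their SE from this model, levels as mean with SD over 3 arrays, relative to the 75th percentile of the array. Where every probe of a gene lay below background on all arrays of one group, the fold is given as a bound ("at least"). It sets each array of that group to the dimmest signal still flagged as well above background on it, or to the gene's own signal if that was higher. Medians of lists were also computed with such a floor.

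Before the data were examined, 18 gene lists and 4 lists of markers of other organs or cell types were fixed: the AHP family, type-A response regulators, cytokinin receptors with type-B response regulators, cytokinin metabolism, dehydration and abscisic acid (ABA) induced genes, ABA metabolism and core signalling, photosynthesis, leaf senescence, flavonoids and anthocyanins, salicylic acid and defence, jasmonate, glucosinolate synthesis, aquaporins, cuticular wax, expansins and xyloglucan enzymes, cell cycle, heat shock, circadian clock, and markers of flowers, roots, guard cells with the stomatal lineage, and seed storage. Each list with at least 3 measured genes was compared with all other genes by camera (preset correlation 0.01), adjusted over the 21 lists of a comparison, and again with a correlation estimated for each list. Of the 4 seed storage genes, 0 were measured.

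The genes named were also chosen by a rule fixed before the data were examined: AHP2, AHP3 and AHP5; for each comparison the 6 largest rises and 6 largest falls among called genes with a symbol whose arrays did not overlap between the groups (chance alone separates 10% of genes with 3 arrays against 3); and for each list up to 4 called members with the largest change, or the 2 with the lowest p. Fewer are printed here, and for genes so chosen the values of other comparisons may stand beside them. Symbols follow the reference table, where RR5, RR16 and RR17 are ARR5, ARR16 and ARR17. Genes of DNA replication and leaf growth, and genes of iron deficiency, were listed only after values had been seen.

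The 12 arrays sat on 4 slides. Slide 1 held the droughted wild type, slide 2 the droughted mutant, slide 3 the 3 watered wild-type arrays with 1 watered mutant array, and slide 4 the other 2 watered mutant arrays. Slide and group can therefore be separated only for the watered genotypes, where slide was also fitted as a fixed block. Replicate numbers did not pair the arrays: deviations from the group means, correlated across genes between arrays of different groups, had a median r of -0.0387 for arrays with the same number and 0.0229 for the others.

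Other settings chosen before the data were examined were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, only genes above background on all 12 arrays, the mean over the probes of a gene, slide as a random or fixed block, array position as a block, replicate number as a block, a trended and robust prior, only the groups of the comparison, the authors' value table, a 2-fold minimum, and each array left out in turn. Scaling to the spike-in probes was added after the data had been seen, as was the comparison of response sizes over genes chosen on the mean of both responses. The model was tested on simulated arrays in which each of the 21255 genes kept its own mean and residual spread, with 50 genes changed for each size. For drought in the wild type it recovered 64% of genes changed by 1 log2 unit and 82% of those changed by 2, and for the watered genotypes 58% and 74%. For the difference of responses it recovered 34% and 60%. Each simulation changed 200 of the 21255 genes, far fewer than were called in the data. The adjusted threshold is stricter with so few, so these shares do not tell how much was missed in the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.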

Results

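Transcript levels were measured in rosette leaves of wild-type Arabidopsis and of ahp2,3,5, a mutant in 3 histidine phosphotransfer proteins that pass the cytokinin signal from the receptors to the response regulators. Plants were kept watered or went without water for 10 days, with 3 arrays for each of the 4 groups. Between 66.5 and 73.7% of spots were well above background on each array, and 21255 genes were tested. Arrays of the same group correlated across genes with r between 0.978 and 0.992. The first principal component held 72.7% of the variance and ran from the droughted wild type (-224 to -217) through the droughted mutant (-54.9 to -23.0) to the watered wild type (102 to 111) and the watered mutant (144 to 151). The median signal was lower on the droughted wild-type arrays (130 to 135) than on all others (265 to 370). Because the median gene moved with the scaling, the share of genes that rose or fell depends on it. The median log2 change over all genes was -0.03 for drought in the wild type, 0.62 with median scaling, 0.12 with quantile normalization, 0.18 with normexp correction and -0.59 with scaling to spike-ins.

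The levels of AHP2, AHP3 and AHP5 were examined first, as a check of the genotype labels. All 3 were lower in the mutant. In watered plants AHP3 (AT5G39340) differed by a log2 value of -7.18 ± 0.63 (SE, n = 3 arrays per group; limma adjusted p = 0.000142), AHP2 (AT3G29350) by -3.38 ± 0.14 (adjusted p = 2.69e-06) and AHP5 (AT1G03430) by -2.44 ± 0.18 (adjusted p = 5.41e-05). Under drought the differences were -9.37, -3.55 and -1.36. AHP3 was above background on 1 of 3 arrays of the droughted mutant, and its second probe differed by -6.74 in watered plants. AHP5 stayed measurable in the mutant, at -4.42 ± 0.35 (SD) when watered and -2.94 ± 0.23 under drought, and it rose there with drought by 1.48 ± 0.18 (SE). Where the probes lie relative to the insertions is not given in the sources used here, so a remaining signal does not tell whether a working transcript was left.

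**Figure D1:**
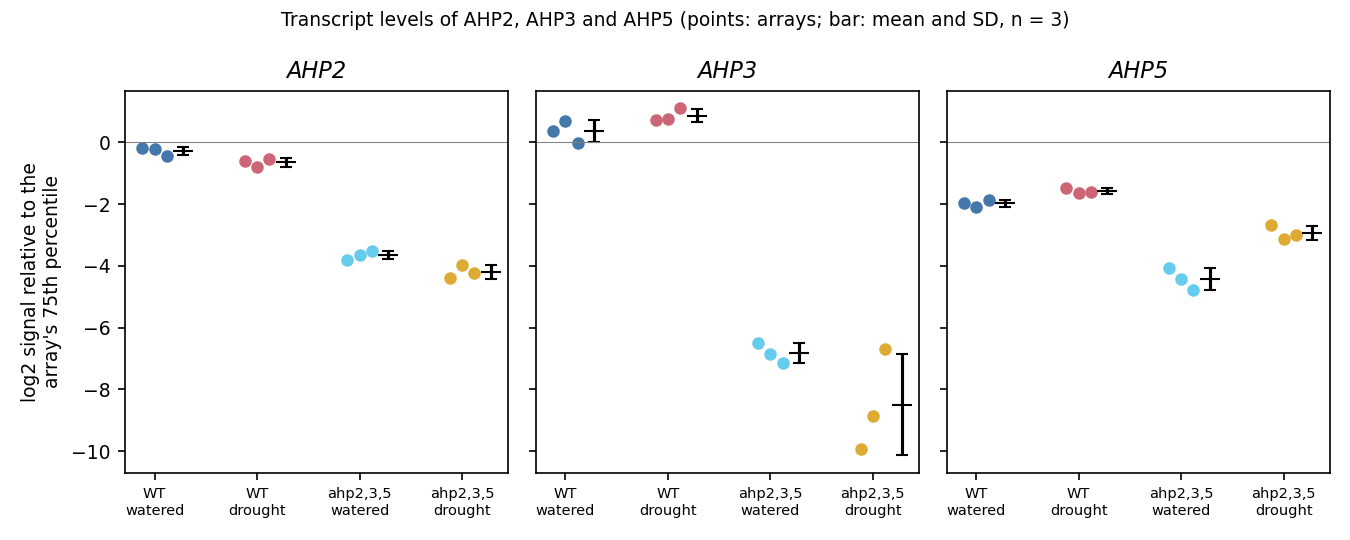
Log2 level of AHP2, AHP3 and AHP5 on each array, relative to the 75th percentile of that array, in the 4 groups of 3 arrays. For all 3 genes the mutant arrays lie below the wild-type arrays, while AHP5 stays closest to the wild type under drought.

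Drought in the wild type asks which leaf genes respond to 10 days without water. LEA7, a gene for a late embryogenesis abundant protein of drying cells, rose by 13.83 ± 0.44 (log2, SE, n = 3 arrays per group; adjusted p = 3.8e-09), and LEA4-5 rose by 11.17 ± 0.30. SAG29, a sugar transporter gene of senescing leaves, rose at least 4745-fold, since all watered arrays were below background. Among the deepest falls, PCC1, a gene of defence and flowering time, fell by 12.33 ± 0.59, and PDF1.2, a defensin gene of the jasmonate and ethylene response, fell at least 1198-fold. In all, 16130 genes changed, 7825 up and 8305 down, and 10330 of them by at least 2-fold. More went up than down with quantile normalization (8707 and 7577), normexp correction and median scaling, and 3917 went up and 10888 down with spike-in scaling. The arrays of both groups did not overlap for 78.4% of genes, where chance gives 10%. Drought and slide cannot be told apart here, since no slide held both groups.

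By function, genes of water shortage rose and those of photosynthesis, water channels, growth and defence fell. Of 28 dehydration and ABA-induced genes 26 rose and 0 fell, both over all genes and adjusted over the list alone, with a median of 3.93 (adjusted p = 9.98e-11, and adjusted p = 0.226 with an estimated correlation). LTI30, a dehydrin gene, rose by 9.51 ± 0.27. Of 29 genes of ABA metabolism and core signalling 18 rose and 7 fell (the same counts adjusted over the list alone), with a median of 0.66 (adjusted p = 0.0201, and adjusted p = 0.371 with an estimated correlation). The median was 1.23 with quantile normalization, 1.31 with median scaling and 0.10 with spike-in scaling, where 12 rose and 7 fell. The phosphatase genes HAI1 and HAI2, which dampen ABA signalling, rose by 7.53 ± 0.26 and 6.67 ± 0.24. Of 36 photosynthesis genes 33 fell and 0 rose (also adjusted over the list alone), with a median of -2.98 (adjusted p = 9.98e-11, and adjusted p = 0.347 with an estimated correlation), led by the small Rubisco subunits RBCS2B, which fell by 6.50 ± 0.25, and RBCS3B, which fell by 6.43 ± 0.25. Of 14 senescence genes 10 rose and 2 fell, adjusted over the list alone as well, with a median of 2.29 (adjusted p = 0.0117, and adjusted p = 0.347 with an estimated correlation). NYE1 and ACD1, which break down chlorophyll, rose by 3.01 ± 0.14 and 3.00 ± 0.17, while the regulator WRKY53 fell by 5.01 ± 0.40.

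All 20 genes of glucosinolate synthesis fell (20 adjusted over the list alone), with a median of -6.37 (adjusted p = 3.51e-07, and adjusted p = 0.226 with an estimated correlation). CYP83B1, an enzyme of the indole branch, fell by 7.61 ± 0.22, and CYP79F1, of the aliphatic branch, fell by 8.72 ± 0.49. Of 20 salicylic acid and defence genes 17 fell and 0 rose (17 adjusted over the list alone), with a median of -4.12 (adjusted p = 0.000215, and adjusted p = 0.371 with an estimated correlation). The pathogenesis-related gene PR5 fell by 7.20 ± 0.38. Of 20 jasmonate genes 14 fell and 2 rose (the same counts adjusted over the list alone), with a median of -1.70, or -1.04 with median scaling (adjusted p = 0.0117, and adjusted p = 0.371 with an estimated correlation). LOX2, which makes jasmonate precursors in the chloroplast, fell by 8.84 ± 0.19. Of 16 aquaporin genes 14 fell and 1 rose, adjusted over the list alone as well, with a median of -3.87 (adjusted p = 5.83e-05, and adjusted p = 0.371 with an estimated correlation). The tonoplast channel TIP2;2 fell by 7.93 ± 0.24. Of 16 expansin and xyloglucan enzyme genes, which loosen walls, 15 fell and 1 rose (the same counts adjusted over the list alone), with a median of -4.96, or -2.52 with normexp correction (adjusted p = 5.02e-05, and adjusted p = 0.226 with an estimated correlation). EXPA6 fell by 8.81 ± 0.34, and TCH4 rose by 7.35 ± 0.68. Of 15 cell-cycle genes 12 fell and 0 rose (12 adjusted over the list alone), with a median of -1.2, or -0.48 with normexp correction and -0.55 with median scaling (adjusted p = 0.00183, and adjusted p = 0.371 with an estimated correlation). The call of this list ended with normexp correction (adjusted p = 0.0890). The D-type cyclin CYCD3;1 fell at least 12.7-fold.

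Of 9 type-A response regulators, which cytokinin induces and which dampen its signal, 7 fell and 1 rose (the same counts adjusted over the list alone), with a median of -2.08, or -0.69 with normexp correction (adjusted p = 0.0392, and adjusted p = 0.396 with an estimated correlation). The call of this list ended with quantile normalization (adjusted p = 0.0518) and with normexp correction (adjusted p = 0.0890). ARR7 fell by 4.39 ± 0.50 and RR16 (ARR16) fell by 2.39 ± 0.24. Of 9 receptors and type-B response regulators 4 rose and 3 fell (5 and 3 adjusted over the list alone). Their median was 0.46 and their mean -0.10, the test was not called (adjusted p = 0.553), and with spike-in scaling 1 rose and 3 fell with a median of -0.10. RR2 rose by 2.2 ± 0.13 and RR14 fell by 3.84 ± 0.22. Of 9 cytokinin metabolism genes 1 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of -2.25 (adjusted p = 0.102), and the synthesis gene IPT3 fell by 4.34 ± 0.34. Of the 5 measured AHP genes 1 rose and 1 fell (0 adjusted over the list alone), with a median of 0.51, or -0.05 with spike-in scaling.

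Of 12 clock genes 8 rose and 0 fell (8 adjusted over the list alone), with a median of 1.28, or 1.93 with median scaling and 0.71 with spike-in scaling (adjusted p = 0.0117, and adjusted p = 0.371 with an estimated correlation). The morning gene CCA1 rose by 2.96 ± 0.26. Of 11 genes of guard cells and the stomatal lineage 7 fell and 1 rose (the same counts adjusted over the list alone), with a median of -1.69 that became -0.43 with dim values set to the floor, -0.30 with normexp correction and -1.04 with median scaling (adjusted p = 0.0485, and adjusted p = 0.505 with an estimated correlation), and with normexp correction 4 rose and 3 fell and the call ended (adjusted p = 0.406). MYB60, a guard-cell regulator, fell by 3.45 ± 0.24. The other lists were not called: flavonoids and anthocyanins (9 of 17 rose, 3 fell; adjusted p = 0.240), heat shock (7 of 10 rose, 1 fell; adjusted p = 0.0533) and cuticular wax (5 of 14 rose, 8 fell; adjusted p = 0.465; median -0.42, or 0.24 with median scaling). Their counts were the same adjusted over the list alone. Among flower genes 2 of 7 rose and 2 fell, with a median of -0.35 that was 0.32 with normexp correction, 0.27 with quantile normalization and 0.30 with median scaling. Among 3 root genes 0 rose and 1 fell, but with normexp correction 1 rose and 0 fell. Of the 4 seed storage genes 0 were measured.

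Drought in the mutant asks how leaves with less AHP2, AHP3 and AHP5 transcript than the wild type respond. LEA7 rose by 14.46 ± 0.44 (adjusted p = 1.15e-08) and SAG29 rose by 13.60 ± 0.31, both above background on 1 of 3 watered arrays, and CWINV5, a cell-wall invertase gene, rose at least 866-fold. The expansin gene EXPA8, above background on 2 of 3 droughted arrays, fell by 9.58 ± 0.36, and PRE1, a growth-promoting regulator, fell at least 68.3-fold. In all, 12688 genes changed, 6417 up and 6271 down (7188 and 4652 with spike-in scaling), and 6328 of them by at least 2-fold. Arrays did not overlap for 71.9% of genes, against 10% by chance. The watered mutant arrays lay on other slides than the droughted ones, so slide could be fitted only as a random block, which does not separate slide from drought.

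Of the 28 dehydration and ABA-induced genes 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 3.47 (adjusted p = 2.42e-12, and adjusted p = 0.147 with an estimated correlation). LTI65 (RD29B) rose by 8.57 ± 0.30. Of 17 flavonoid and anthocyanin genes 16 rose and 0 fell (16 adjusted over the list alone), with a median of 4.34 (adjusted p = 3.36e-06, and adjusted p = 0.228 with an estimated correlation). DFR and LDOX, late enzymes of anthocyanin synthesis, rose by 10.47 ± 1.28 and 9.44 ± 0.96, with DFR above background on 2 of 3 watered arrays. All 9 type-A response regulators fell (9 adjusted over the list alone), with a median of -2.50 (adjusted p = 0.000126, and adjusted p = 0.302 with an estimated correlation). RR16 fell by 5.37 ± 0.24. Of the photosynthesis genes 34 fell and 0 rose (34 adjusted over the list alone), with a median of -1.28 (adjusted p = 1.47e-10, and adjusted p = 0.302 with an estimated correlation). LHCB3, of the light-harvesting antenna, fell by 2.81 ± 0.22. Of the defence genes 19 fell and 0 rose (19 adjusted over the list alone), with a median of -2.65 (adjusted p = 7.77e-06, and adjusted p = 0.302 with an estimated correlation). BGL2 (PR2) fell by 3.99 ± 0.35. Of the glucosinolate genes 16 fell and 0 rose (16 adjusted over the list alone), with a median of -1.38 (adjusted p = 0.000126, and adjusted p = 0.302 with an estimated correlation).

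Growth genes fell here as well. Of the expansin and xyloglucan genes 14 fell and 1 rose (the same counts adjusted over the list alone), with a median of -3.75 (adjusted p = 4.48e-06, and adjusted p = 0.217 with an estimated correlation). EXPA6 fell by 5.00 ± 0.34. Of the aquaporins 13 fell and 2 rose, adjusted over the list alone as well, with a median of -2.47 (adjusted p = 5.18e-05, and adjusted p = 0.302 with an estimated correlation). Of the cell-cycle genes 10 fell and 0 rose (10 adjusted over the list alone), with a median of -0.96 (adjusted p = 0.0035, and adjusted p = 0.438 with an estimated correlation). CYCD3;1 fell by 2.46 ± 0.27. Of the stomatal genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.54, or -0.67 with normexp correction (adjusted p = 0.00278, and adjusted p = 0.354 with an estimated correlation). Of the heat shock genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.84, or 0.72 with normexp correction (adjusted p = 0.0342, and adjusted p = 0.315 with an estimated correlation). The call of this list ended with normexp correction (adjusted p = 0.104). The small heat shock gene HSP21 rose at least 53.1-fold.

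The remaining lists were not called in the mutant. Of the ABA genes 18 rose and 9 fell (19 and 9 adjusted over the list alone; adjusted p = 0.108), of the senescence genes 7 rose and 4 fell (7 and 5 adjusted over the list alone; adjusted p = 0.453), and of the cytokinin metabolism genes 2 rose and 6 fell (the same adjusted over the list alone; adjusted p = 0.130). Of the jasmonate genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; adjusted p = 0.980), with a median of 0.02 and a mean of -0.03, and more rose than fell with normexp correction, quantile normalization, median scaling and spike-in scaling. Counts over all genes and adjusted over the list alone were equal for the rest. Clock genes (3 rose, 1 fell), wax genes (2 rose, 5 fell), receptors and type-B regulators (2 rose, 3 fell), AHP genes (2 rose, 2 fell), flower genes (2 rose, 1 fell) and root genes (1 rose, 1 fell) moved both ways. The median of the receptors and type-B regulators was -0.09, but 0.05 with median scaling and 0.10 with spike-in scaling.

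**Figure D2:**
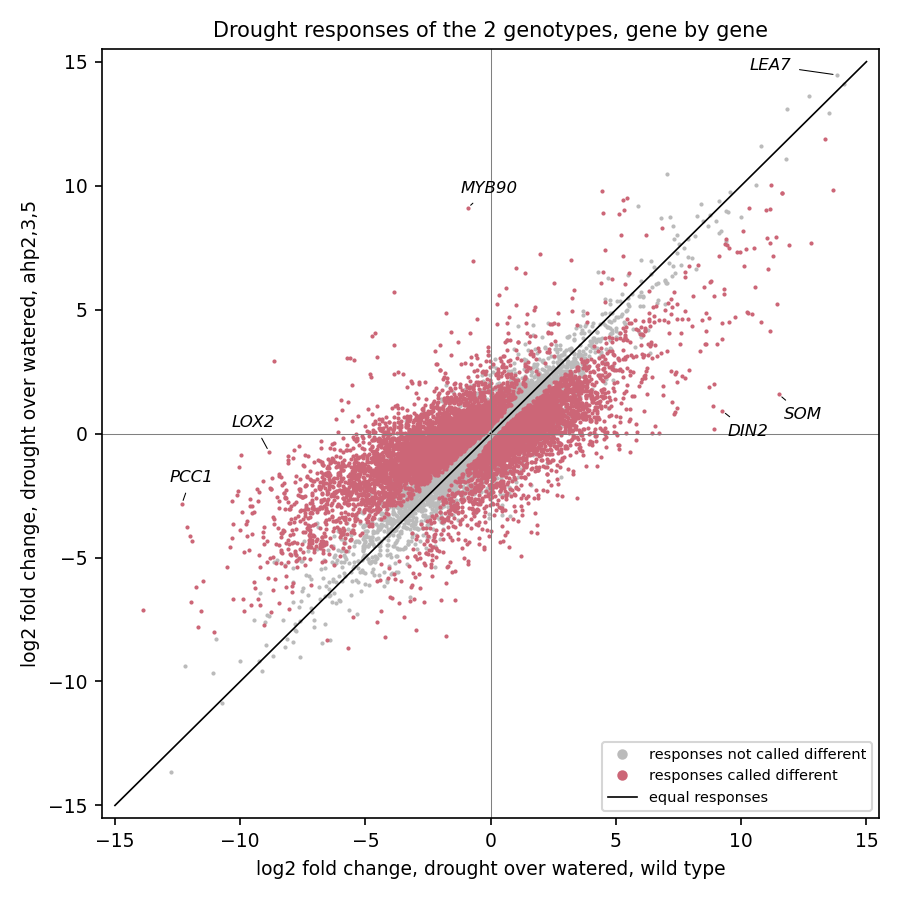
Drought response (log2 fold change) of each of 21255 genes in the wild type and in ahp2,3,5, from 3 arrays per group. Values spread wider in the wild type than in the mutant.

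The drought responses of the genotypes were set side by side to ask how far the response depends on the 3 AHP genes. Across genes they correlated with r = 0.754 (rho 0.681), with a standard deviation of 2.3 in the wild type and 1.58 in the mutant, and genes are not independent replicates. Of the genes called up in the wild type 4557 were also called up in the mutant, where 2362 would be shared if calls were independent, and 4841 were down in both (2450 if independent). Of 8226 genes with a mean response of at least 2-fold over both genotypes, where equal responses would give 50%, 79.3% had the smaller response in the mutant, with medians of 2.52 in the wild type and 1.44 in the mutant. That share was 78.6% with quantile normalization, 81.6% with median scaling and 78.6% with spike-in scaling. With spike-in scaling it was 54.6% of the rises and 89.0% of the falls. Choosing genes by the response of 1 genotype favours that genotype: of the 10330 genes that changed at least 2-fold in the wild type 89.2% had a smaller response in the mutant, while of the 6328 chosen in the mutant 40.5% had a smaller response in the wild type. The test of the difference itself called 11431 of all genes, 6150 with a higher and 5281 with a lower value in the mutant, and 7016 differed at least 2-fold. With spike-in scaling 10412 were higher and 1189 lower, and with normexp correction and median scaling more were lower than higher. Slide and group cannot be told apart in this comparison. The median difference over all genes was 0.03, but -0.18 with normexp correction, -0.48 with median scaling and 0.79 with spike-in scaling, so directions of small differences depend on the scaling.

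Among single genes, MYB90 (PAP2), an activator of anthocyanin synthesis, had the highest difference at 10.02 ± 1.05 (SE; adjusted p = 4.82e-05). It rose by 9.09 ± 0.75 in the mutant, where 1 of 3 watered arrays was above background, while its value in the wild type was -0.92 ± 0.75 and not called, running from -1.71 without replicate 2 of the droughted wild type to 0.0534 without replicate 3. The thionin gene THI2.1 rose by 5.72 in the mutant and fell at least 3.04-fold in the wild type, where all droughted arrays were below background, a difference of 7.33 with dim values at the floor, and the call of the fall ended with normexp correction, at -0.22. PCC1 differed by 9.48 ± 0.83, because it fell by 2.85 in the mutant and fell by 12.33 in the wild type. CSLA10, of cell-wall polysaccharide synthesis, and MBP1, a myrosinase-binding protein gene, differed by 8.68 ± 0.54 and 8.39 ± 0.52, both rising in the mutant and falling in the wild type. UMAMIT36, a transporter gene, was below background in the droughted wild type and differed by 6.97 at the floor. In the other direction, SOM, a regulator known from seed germination, rose at least 815-fold in the wild type, since all its watered arrays were below background. In the mutant it was above background on 0 of 3 watered and 1 of 3 droughted arrays, and its difference was -9.50 at the floor. MCT1 and the flowering gene FPF1 were above background in the droughted wild type alone, where they rose at least 142-fold and 51.9-fold, with differences of -7.03 and -5.64 at the floor. The sugar-starvation gene DIN2, below background in the watered mutant, differed by -8.39 at the floor, TCH4 by -6.48 ± 0.96 and the sterol-binding protein gene ORP4C by -6.43 ± 0.51.

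By list, several falls of the wild type were shallower in the mutant. Of 20 glucosinolate genes 19 had a higher value in the mutant and 0 a lower one (19 adjusted over the list alone), with a median difference of 4.74, or 2.95 with normexp correction (adjusted p = 1.29e-07, and adjusted p = 0.415 with an estimated correlation), including CYP79F1 at 6.92 ± 0.70. Of the photosynthesis genes 28 were higher and 1 lower (29 and 1 adjusted over the list alone), with a median of 1.73 (adjusted p = 2.25e-08, and adjusted p = 0.560 with an estimated correlation). RBCS3B differed by 5.31 ± 0.35. The flavonoid list was called for drought in the mutant and not in the wild type, where 9 of its genes rose and 3 fell, and for the difference 12 were higher and 0 lower (12 adjusted over the list alone), with a median of 3.19 (adjusted p = 0.00144, and adjusted p = 0.560 with an estimated correlation), including the activator PAP1 at 5.58 ± 0.76. Of the jasmonate genes 13 were higher and 0 lower (13 and 1 adjusted over the list alone), with a median of 1.72 (adjusted p = 0.00144, and adjusted p = 0.560 with an estimated correlation). LOX2 differed by 8.09 ± 0.27. Of the aquaporins 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.75, or 1.15 with normexp correction (adjusted p = 0.00144, and adjusted p = 0.566 with an estimated correlation). PIP2B (PIP2;2) differed by 4.43 ± 0.55.

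Of the expansin and xyloglucan genes 9 were higher and 1 lower (the same counts adjusted over the list alone), with a median of 1.71 that was 0.36 at the floor (adjusted p = 0.04, and adjusted p = 0.566 with an estimated correlation), but with normexp correction 5 were higher and 8 lower with a median of -0.27, and the call ended (adjusted p = 0.963). Of the cell-cycle genes 9 were higher and 1 lower, adjusted over the list alone as well, with a median of 1.08, or 0.42 with quantile normalization, 0.57 with median scaling and 1.83 with spike-in scaling (adjusted p = 0.04, and adjusted p = 0.656 with an estimated correlation), but with normexp correction 0 were higher and 5 lower with a median of -0.38, and the call ended (adjusted p = 0.781), as it did with quantile normalization (adjusted p = 0.103). Of the dehydration and ABA-induced genes 16 were lower and 1 higher (the same counts adjusted over the list alone), with a median of -0.74 (adjusted p = 0.00144, and adjusted p = 0.560 with an estimated correlation), but the median was -0.09 with quantile normalization, where the call ended (adjusted p = 0.374), -1.25 with median scaling and 0.02 with spike-in scaling. ADH1, of anaerobic metabolism, differed by -3.05 ± 0.39. Of the clock genes 5 were lower and 0 higher (5 adjusted over the list alone), with a median of -0.50 (adjusted p = 0.0367, and adjusted p = 0.580 with an estimated correlation), or -1.01 with median scaling and 0.26 with spike-in scaling. The call of the clock list ended with normexp correction (adjusted p = 0.161). PRR9, below background on all arrays of the other 3 groups, was at least 25.7-fold higher in the droughted than in the watered wild type, and its difference with dim values at the floor was -4.63.

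The lists that follow were not called for the difference of responses. Of the ABA genes 7 were higher and 13 lower (the same adjusted over the list alone; adjusted p = 0.0826), with a median of -0.33 that was 0.42 with spike-in scaling. Of the senescence genes 3 were higher and 7 lower (3 and 9 adjusted over the list alone; adjusted p = 0.0882), and of the defence genes 8 were higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0886). Of the type-A response regulators 1 was higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.323), but with spike-in scaling 3 were higher and 2 lower. RR5 (ARR5) differed by -2.41 ± 0.22 and RR16 by -2.99 ± 0.34. Cytokinin metabolism had 4 higher and 1 lower (4 and 2 adjusted over the list alone), the receptors and type-B regulators 2 and 4 (spike-in scaling 3 and 1), the AHP genes 1 and 0 (median scaling 0 and 2), wax 5 and 3 (5 and 4 adjusted over the list alone; normexp correction 3 and 4), heat shock 0 and 1 (0 and 0 adjusted over the list alone; spike-in scaling 1 and 0), stomatal genes 2 and 3, flower genes 1 and 0, and root genes 1 and 0 (normexp correction 0 and 1). The wax median was -0.01 and its mean 0.51, and the median of the AHP genes was -0.17 while their test pointed up. The heat shock median was 0.07, while its test pointed down.

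Mutant against wild type in watered plants asks what differs in the mutant of the same age when no water is withheld. Besides the AHP genes, MRD1 was lower by a log2 value of -6.16 ± 0.30 (adjusted p = 1.3e-05). ADS4, a fatty acid desaturase gene, was at least 16.9-fold higher. BHLH100, a regulator of the iron-deficiency response, was higher by 5.6 ± 1.2, and TT4 (chalcone synthase), which opens the flavonoid pathway, by 4.35 ± 0.65. With slide as a fixed block both calls ended, at 4.72 and 4.30. In all, 5382 genes differed, 3046 higher and 2336 lower, but 1144 higher and 4673 lower with spike-in scaling, and 2098 differed at least 2-fold. Arrays did not overlap for 42.2% of genes, against 10% by chance. Without replicate 3 of the watered mutant 2931 genes were called, and without replicate 3 of the watered wild type 3328. One slide held 3 wild-type arrays and 1 mutant array. Values within it use 4 of the 6 arrays of the main comparison, so part of their agreement with it is built in. With slide as a fixed block the difference is this same one, since the other slide held mutant arrays alone. A call that ended with the block may thus reflect the single mutant array rather than the slide. With slide as a fixed block, which leaves 3 residual degrees of freedom, 753 genes were called, 515 of them among the 5382, and of 80 genes examined singly 11 stayed called and 69 did not. The median difference over all genes was 0.00, and -0.31 with spike-in scaling.

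Growth and surface genes were higher in the watered mutant. Of 15 cell-cycle genes 12 were higher and 0 lower (13 adjusted over the list alone), with a median of 1.36, or 1.19 within the shared slide (adjusted p = 2.74e-06, and adjusted p = 0.303 with an estimated correlation). CYCD3;1 was higher by 1.82 ± 0.27, a call that ended with slide as a fixed block, at 1.75. Of 16 expansin and xyloglucan genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 1.82, or 1.53 within the slide (adjusted p = 2.74e-06, and adjusted p = 0.118 with an estimated correlation). XTH8, which remodels xyloglucan, was higher by 2.70 ± 0.17 and stayed called with slide as a block. Of 14 wax genes 9 were higher and 0 lower (10 adjusted over the list alone), with a median of 0.82, or 0.86 within the slide and 0.51 with spike-in scaling (adjusted p = 3.94e-05, and adjusted p = 0.303 with an estimated correlation). CER1 and CYP96A15 (MAH1), enzymes of alkane synthesis and oxidation, were higher by 2.82 ± 0.35 and 3.44 ± 0.51, and both stayed called with slide as a block.

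Of 14 senescence genes 9 were lower and 0 higher (10 adjusted over the list alone), with a median of -1.02, or -0.99 within the slide (adjusted p = 1.02e-05, and adjusted p = 0.118 with an estimated correlation). SEN1, induced in darkness and ageing, differed by -2.96 ± 0.36, the regulator NAP by -2.32 ± 0.29 and SAG21 by -2.19 ± 0.20, and all 3 stayed called with slide as a block. Of 9 type-A response regulators 3 were higher and 0 lower (4 adjusted over the list alone), with a median of 0.70, or 0.46 within the slide and 0.39 with spike-in scaling (adjusted p = 0.00896, and adjusted p = 0.487 with an estimated correlation). RR5 was higher by 1.01 ± 0.16 and stayed called with slide as a block, while ARR15, at 1.99 ± 0.27, did not, at 1.95 with the block. Of the 5 AHP genes 3 were lower and 0 higher (3 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.118 with an estimated correlation), and these are AHP2, AHP3 and AHP5 themselves, so the list repeats the check of the genotype. Of the photosynthesis genes 13 were higher and 0 lower (13 adjusted over the list alone), with a median of 0.32 (adjusted p = 4.36e-05, and adjusted p = 0.497 with an estimated correlation). The median was 0.18 within the slide and with quantile normalization and 0.01 with spike-in scaling, where 2 were higher and 0 lower. Of the aquaporins 4 were higher and 0 lower (6 adjusted over the list alone), with a median of 0.59, or 0.57 within the slide and 0.28 with spike-in scaling (adjusted p = 0.00894, and adjusted p = 0.497 with an estimated correlation). Of the stomatal genes 5 were higher and 0 lower (5 adjusted over the list alone), with a median of 1.11, or 0.61 within the slide and 0.55 with normexp correction (adjusted p = 0.022, and adjusted p = 0.497 with an estimated correlation).

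Smaller list differences were also called in watered plants. Dehydration genes had 5 higher and 8 lower (5 and 10 adjusted over the list alone), with a median of -0.19, or -0.08 within the slide, -0.32 with quantile normalization and -0.51 with spike-in scaling (adjusted p = 0.0497, and adjusted p = 0.497 with an estimated correlation). Jasmonate genes had 0 higher and 3 lower (2 adjusted over the list alone), with a median of -0.38, or -0.23 within the slide and -0.69 with spike-in scaling (adjusted p = 0.0361, and adjusted p = 0.497 with an estimated correlation). Flower genes had 0 higher and 2 lower (3 adjusted over the list alone), with a median of -0.42, or -0.45 within the slide and -0.73 with spike-in scaling (adjusted p = 0.0209, and adjusted p = 0.363 with an estimated correlation). Not called were ABA genes (3 higher, 7 lower; 3 and 9 adjusted over the list alone; adjusted p = 0.0543), flavonoids (5 and 2; adjusted p = 0.0634), defence (0 and 2; 0 and 0 adjusted over the list alone; adjusted p = 0.0634), clock (0 and 2; adjusted p = 0.0634), glucosinolates (0 and 2; 0 and 1 adjusted over the list alone; adjusted p = 0.116), cytokinin metabolism (1 and 2), receptors and type-B regulators (2 and 3), heat shock (1 and 0; 0 and 0 adjusted over the list alone) and root (1 and 0). The clock gene GI, at -1.14 ± 0.15, and the cytokinin oxidase gene CKX1, at -1.23 ± 0.24, stayed called with slide as a block. The medians of the receptors and of heat shock, 0.08 and 0.04, were -0.23 and -0.27 with spike-in scaling, and the test of the receptors pointed down. The root median was -0.81, while its test pointed up.

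The mutant effect in watered plants was compared with the wild-type drought response to ask whether the mutant resembles a droughted or a well-watered plant. Across genes they correlated with r = -0.226 (rho -0.276), with an SE of 0.071 from leaving out each of the 12 arrays. The value ran from -0.250 without replicate 1 to -0.162 without replicate 2 of the watered wild type. The shared watered wild-type arrays alone gave a simulated covariance of 0.0513, against -0.386 in the data. The simulated r of 0.499 holds for values without real differences, so it cannot be set beside the observed r. Of genes higher in the watered mutant 1951 fell with drought in the wild type, where 1190 would be shared if calls were independent, and of genes lower in it 1274 rose with drought (860 if independent).

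**Figure D3:**
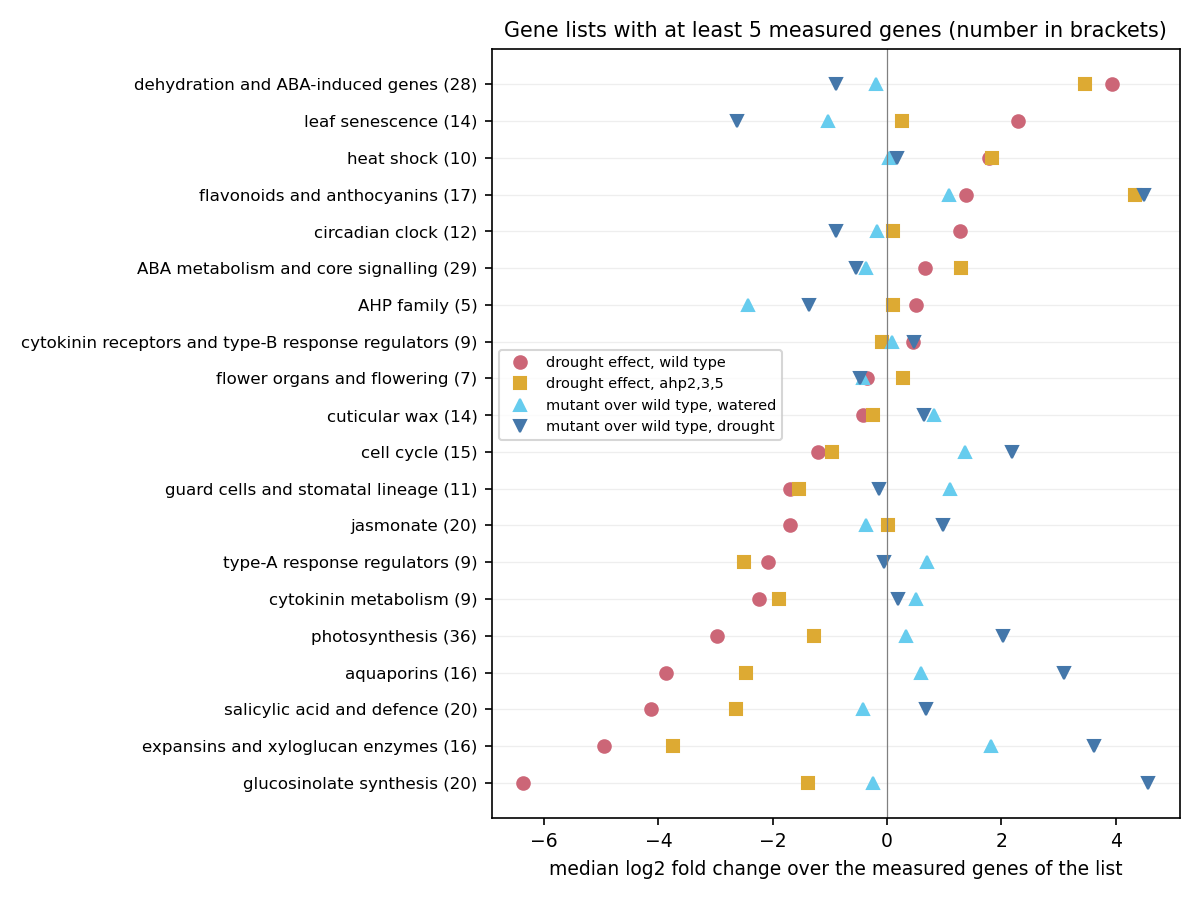
Median log2 fold change over the measured genes of each list with at least 5 of them (number in brackets), for drought in each genotype and for ahp2,3,5 over the wild type in each watering, from 3 arrays per group. Glucosinolate genes lie at -6.37 for drought in the wild type and at -1.38 in the mutant, and the flower, wax, AHP, receptor, heat shock, cytokinin metabolism, type-A and guard-cell medians turn direction under at least 1 other scaling in at least 1 comparison.

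Mutant against wild type under drought asks how the genotypes differ once water is withheld. ESM1, which directs glucosinolate breakdown, was higher in the mutant by 9.52 ± 0.34 (adjusted p = 3.87e-08; above background on 2 of 3 wild-type arrays), ENODL19, an early nodulin-like gene, by 8.51 ± 0.34, and the flavonol regulator MYB111 at least 118-fold. Lower were MPL1, a lipase gene, at -8.54 ± 0.30, and DOX1, which oxidises fatty acids, at least 210-fold. In all, 15030 genes differed, 7876 higher and 7154 lower, and 8522 at least 2-fold. More were lower than higher with quantile normalization (7717 and 7130), normexp correction and median scaling, and 9950 were higher and 3347 lower with spike-in scaling. Arrays did not overlap for 79.5% of genes, against 10% by chance. The genotypes sat on separate slides, so slide and genotype cannot be told apart. The median difference over all genes was 0.01, with -0.16 after normexp correction, -0.52 with median scaling and 0.45 with spike-in scaling.

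Genes of photosynthesis and secondary metabolism were higher in the droughted mutant. Of 36 photosynthesis genes 34 were higher and 0 lower (34 adjusted over the list alone), with a median of 2.04 (adjusted p = 9.12e-10, and adjusted p = 0.326 with an estimated correlation). RBCS3B was higher by 5.36 ± 0.25. All 17 flavonoid genes were higher (17 adjusted over the list alone), with a median of 4.49, or 4.11 at the floor (adjusted p = 0.000157, and adjusted p = 0.282 with an estimated correlation). PAP1 was higher by 5.72 ± 0.54. Of 20 glucosinolate genes 19 were higher and 0 lower (19 adjusted over the list alone), with a median of 4.57 (adjusted p = 9.77e-06, and adjusted p = 0.282 with an estimated correlation). CYP79F1 was higher by 6.44 ± 0.49. Of the jasmonate genes 13 were higher and 2 lower (the same adjusted over the list alone), with a median of 0.99, or 0.45 with median scaling (adjusted p = 0.0222, and adjusted p = 0.475 with an estimated correlation). LOX2 was higher by 8.02 ± 0.19. Of the aquaporins 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 3.1, or 2.18 at the floor and 1.56 with normexp correction (adjusted p = 0.000157, and adjusted p = 0.336 with an estimated correlation). TIP2;2 was higher by 4.44 ± 0.24.

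Of the expansin and xyloglucan genes 12 were higher and 2 lower (the same adjusted over the list alone), with a median of 3.63 (adjusted p = 0.00155, and adjusted p = 0.282 with an estimated correlation). The median was 2.37 at the floor and 1.07 with normexp correction, where 9 were higher and 3 lower. EXPA6 was higher by 5.04 ± 0.34. Of the cell-cycle genes 12 were higher and 1 lower (the same adjusted over the list alone), with a median of 2.2, or 2.1 at the floor and 0.84 with normexp correction (adjusted p = 0.00059, and adjusted p = 0.336 with an estimated correlation). CYCB1;3 was at least 12.4-fold higher. Of the wax genes 8 were higher and 0 lower (8 adjusted over the list alone), with a median of 0.65, or 0.12 with median scaling and 1.1 with spike-in scaling (adjusted p = 0.0451, and adjusted p = 0.476 with an estimated correlation). CER2 was higher by 4.88 ± 0.26. In the other direction, 19 of 28 dehydration and ABA-induced genes were lower and 1 higher (20 and 2 adjusted over the list alone), with a median of -0.89, or -0.33 with quantile normalization, -1.43 with median scaling and -0.45 with spike-in scaling (adjusted p = 0.000157, and adjusted p = 0.282 with an estimated correlation). DREB2A, a regulator of the dehydration response, differed by -2.44 ± 0.18. Of the ABA genes 18 were lower and 5 higher (the same adjusted over the list alone), with a median of -0.55 (adjusted p = 0.0168, and adjusted p = 0.336 with an estimated correlation). The median was -1.08 with median scaling and -0.10 with spike-in scaling, where 8 were lower and 8 higher. AAO3, of ABA synthesis, differed by -2.35 ± 0.14. Of the senescence genes 11 were lower and 3 higher (the same adjusted over the list alone), with a median of -2.63 (adjusted p = 0.00348, and adjusted p = 0.282 with an estimated correlation). SEN1 differed by -5.82 ± 0.36. Of the clock genes 9 were lower and 0 higher (9 adjusted over the list alone), with a median of -0.90, or -1.43 with median scaling and -0.45 with spike-in scaling (adjusted p = 0.00318, and adjusted p = 0.336 with an estimated correlation). ELF4 differed by -1.77 ± 0.15.

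The cytokinin lists were not called under drought. Of the type-A response regulators 3 were higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.951), with a median of -0.05 and a mean of 0.12, or a median of 0.40 with spike-in scaling. RR16 differed by -2.69 ± 0.24 and RR3 (ARR8) by 1.46 ± 0.16. Of the receptors and type-B regulators 3 were higher and 4 lower (the same adjusted over the list alone; adjusted p = 0.700), with a median of 0.48 while their test pointed down, and with spike-in scaling 5 were higher and 4 lower. RR2 differed by -2.56 ± 0.13 and RR14 by 3.50 ± 0.22. Of the cytokinin metabolism genes 4 were higher and 2 lower (4 and 1 adjusted over the list alone; adjusted p = 0.419), with a median of 0.19, or -0.06 with normexp correction and -0.35 with median scaling. Of the AHP genes 1 was higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.0807). Defence genes (11 higher, 4 lower; 11 and 5 adjusted over the list alone), heat shock (2 and 2; 1 and 2 adjusted over the list alone), flower genes (0 and 1; 0 and 0 adjusted over the list alone), root genes (2 and 0, but 0 and 1 with normexp correction) and stomatal genes (4 and 2; 4 and 1 adjusted over the list alone; 2 and 4 with normexp correction, 4 and 5 with median scaling) were not called either. The stomatal median was -0.15 and its mean 0.56, and the heat shock median was 0.18, or -0.14 with normexp correction. The mutant effects in watered and droughted plants correlated across genes with r = 0.488, with 2099 genes higher in both (1129 if calls were independent) and 1485 lower in both (786 if independent).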

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

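Of the tests in this part, those of slide, scaling, RNA quality and cytokinin output were chosen in this form only after the result was seen, as were the lists behind the test of young tissue.

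A test of the difference between the drought responses of the genotypes called 11431 genes, and this difference between groups is why the results that follow are taken up here. The highest differences (mutant minus wild type, log2) were those of MYB90 at 10.02, THI2.1 at 9.59, PCC1 at 9.48, UMAMIT36 at 8.77, CSLA10 at 8.68 and MBP1 at 8.39. The lowest were those of SOM at -9.91, DIN2 at -8.32, MCT1 at -7.77, FPF1 at -6.56, TCH4 at -6.48 and ORP4C at -6.43. In at least 1 group THI2.1, UMAMIT36, SOM, DIN2, MCT1 and FPF1 were below background on all arrays, and with dim values at the floor they differed by 7.33, 6.97, -9.50, -8.39, -7.03 and -5.64. Lists called higher had medians of 4.74 for glucosinolate synthesis, 3.19 for flavonoids, 1.75 for aquaporins, 1.73 for photosynthesis, 1.72 for jasmonate, 1.71 for expansins and xyloglucan enzymes and 1.08 for the cell cycle, of which the last 2 turn with normexp correction. Lists called lower had medians of -0.74 for dehydration and ABA-induced genes and -0.50 for the clock, and both medians turn with spike-in scaling. None of these list calls held with an estimated correlation.

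Other splits of the arrays were tried for the difference of responses. Among 100 splits, 5 gave at least 11431 genes, the real one included, so chance is not excluded by this count. The other 4 all kept the droughted genotypes whole, so they are no measure of chance either. The highest of them, at 14339, kept the watered genotypes whole as well. The splits with many calls have a structure: 13 kept the droughted genotypes whole and gave 9844 to 14339 genes, while 86 mixed them and gave 0 to 11. The count thus follows the contrast of the droughted genotypes, which is also a contrast of slides. For the other comparisons the splits of 6 arrays are too few, 10 in each, with 1 as large, the real one. Drought in the wild type called 16130 genes against at most 1 in another split, drought in the mutant 12688 against 2, genotype when watered 5382 against 1 and genotype under drought 15030 against 0. Every other split put arrays of both groups on each side, so the difference between the groups widened the spread within each side. Such low counts were largely set in advance and are no measure of chance. The same holds for the 86 splits that mixed the droughted genotypes.

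The first pattern is the smaller drought response of the mutant. Altered signal on the slide of the droughted wild type is argued against only in the range of the brighter spike-in probes. Of 10 such probes the 7 above a log2 signal of 5 were compared. None of these differed between the droughted genotypes by more than 0.0805 after centring. Dimmer signals, and a shift common to the slide, which centring removes, were not covered by this test. Scaling to the 75th percentile could be part of the cause for rises, chosen on the mean of both responses. The lowest share of them with the smaller response in the mutant was 54.6%, with spike-in scaling, where equal responses give 50%. It was 78.8% with the main scaling, 79.0% with quantile normalization and 88.9% with median scaling. For falls the share was 71.7% with median scaling, 78.3% with quantile normalization and 89.0% with spike-in scaling, so falls were more often smaller in the mutant under each of them. The lowest is under the 75% set for excluding scaling, which thus stays open as part of the cause for falls. A shift common to all genes of an array trades rises for falls and leaves the spread of the responses, a standard deviation of 2.3 in the wild type and 1.58 in the mutant, as it was. Over rises and falls together the share was 79.3% with the main scaling. It was 78.6% with quantile normalization, 81.6% with median scaling and 78.6% with spike-in scaling. Since median and spike-in scaling leave the spread as it was, their shares had little room to change. Of these scalings only quantile normalization could have changed the spread, and the standard deviations were 2.29 and 1.58 with it. Its share of 78.6% argues against scaling as the cause of the smaller response over rises and falls together. Poorer RNA, or a smaller share of mRNA in it, in the droughted wild-type leaves stays open. The 75th percentile relative to spike-ins was higher by 0.44 in the droughted mutant, at 0.25 ± 0.03 (SD) against -0.20 ± 0.22. Per the labels 0.5 µg of RNA was labelled in every group, so this value does not measure the amount of RNA in the leaves. A milder loss of water in the mutant may also underlie the pattern, and leaf water content was not analysed here.

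The second pattern is the higher level of cell-cycle and wall-loosening genes in the watered mutant. The test of a slide difference could not have argued against it, so it stays open for the lists as a whole. Arguing against it was set to need at least 2 mutant arrays in the slide that holds both genotypes, which held 1. The 31 measured members had a median of 1.24 within that slide, where 29 were higher in the mutant, against 1.5 over all arrays. A single mutant array stands behind the first value, and also behind the differences with slide as a fixed block. With that block 3 members stayed called higher, against 25. Those 3, EXP3, EXPA5 and XTH8, are all wall-loosening genes. More young, dividing leaf tissue in the mutant could raise them and stays open: 15 growing-leaf genes had a median of 0.42, but 2 were called higher and 1 lower.

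The third pattern is the higher level of type-A response regulators in a mutant with lower transcript levels of 3 transmitters of the cytokinin signal. Within the shared slide the 9 measured members had a median of 0.46, against 0.70 over all arrays, and 8 were higher in the mutant there. The test of a slide difference could not have argued against it here either, since that slide held 1 mutant array, so it stays open. Slide as a fixed block rests on that same array. With it RR5, at 1.3, was the only 1 of the 3 called members that stayed called, while ARR15 and ARR9 lost their calls, at 1.95 and 0.41. In all 2 members were called higher with the block, and the other had no call without it. A cytokinin output raised as a whole stays open too. The 4 measured cytokinin oxidase genes, which cytokinin induces, had a median of -0.39 but went both ways: CKX1 and CKX5 were called lower, at -1.23 and -2.01, the latter not with slide as a fixed block, at -2.61, and CKX4 and CKX6 were not called, at 0.83 and 0.45. A release of single regulators from another signal may remain, and it was not tested.

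Probes without an assigned gene gave a signal outside the main measurement: of 2617 such probes tested, 1723 changed with drought in the wild type, or 65.8%, against 75.9% of genes.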

How the results depend on the processing

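Scaling to spike-ins was chosen after seeing the data, and all other settings were planned. Over all settings, 321 values of the main results stayed the same and 11 moved. Counts had to stay within 1.5 times the main count, which compares totals and not which genes were called or in which direction. With spike-in scaling both the difference of responses and the watered genotypes stayed within that bound. Yet they kept only 7339 of 11431 and 3480 of 5382 calls in the same direction. With quantile normalization they kept 9661 and 4982. Correlations had to keep their direction and stay within their SE from leaving out arrays. Differences of AHP2, AHP3 and AHP5 had to keep their direction and their side of the adjusted p threshold. For single named genes 10779 values stayed the same, 436 lost their call, 1 gained one and 12 turned. Nearly all of these genes were chosen because they were called, most with large changes. Most were thus bound to stay called and few could gain a call, so this tally does not tell how stable other genes are. Slide as a fixed block, where the difference rests on 1 mutant array, ended the most, 69 of 80. Each other setting ended at most 32 of up to 457. Requiring a 2-fold change left 10330 genes for drought in the wild type, 6328 for drought in the mutant, 2098 for genotype when watered, 8522 for genotype under drought and 7016 for the difference of responses, by construction. The watered genotypes depended most on the setting. They gave 3167 genes with only the groups of the comparison, 753 with slide as a fixed block, which leaves 3 residual degrees of freedom, and 2931 (without ahp235_watered replicate 3) to 5676 when an array was left out, with 3328 without WT_watered replicate 3. Leaving out arrays gave 15292 to 16264 genes for drought in the wild type, 11131 to 13087 for drought in the mutant, 14009 to 15416 for genotype under drought and 10261 to 11496 for the difference. The agreement of the responses was r = 0.719 with only genes above background on all 12 arrays, a smaller set of genes, and 0.728 to 0.764 with an array left out. Of the 57 list calls, 1 of which is the AHP list that repeats the genotype, 0 held with an estimated correlation (lowest adjusted p = 0.118), and 57 held with a replicate block, 57 with slide as a random block (within-slide correlation -0.0553), which says nothing about slides that follow the groups, 54 with quantile normalization and 50 with normexp correction, where 2 turned.

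With normexp correction RR17 (drought in the wild type) became 0.0530. Under drought between genotypes ARR15 became -0.24, NRT2:1 -0.15, CASP1 -0.36 and AT1G22690 -0.0422. For the difference of responses CER4 became -0.0157, HIK -0.16, CYC1BAT -0.0765 and EPF1 -0.49. AHP2 (drought in the wild type) became 0.28 with median scaling, and AGL20 became -0.12 with spike-in scaling. MYB90 (drought in the wild type, not called) ran from -1.71 without WT_drought replicate 2, where it was called lower, to 0.0534 without WT_drought replicate 3. The cause was not tested. Most of these genes were below background in 1 group, where signal over background limits every fold.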

Other observations

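The genes in this part and the test of iron deficiency were chosen only after values were seen. Genes of DNA replication and leaf growth fell with drought in the wild type, 13 of 15, with a median of -3.38. In the mutant 4 fell, with a median of -0.49. The difference of responses was called for 11 of them, all higher in the mutant, with a median of 2.64. Under drought 13 were higher in the mutant than in the wild type, with a median of 3.55. ANT, which keeps leaf cells dividing, fell at least 18.9-fold with drought in the wild type, where all droughted arrays were below background, and was at least 19.6-fold higher in the droughted mutant. MCM2, of the replication helicase, fell by 4.05 and was higher by 3.93, with a difference of responses of 3.55. For ANT and PCNA1 the calls of that difference, 2.93 at the floor and 2.64, ended with normexp correction.

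BHLH100 had the highest rise among genes of the watered mutant that met the naming rule, and an iron-deficiency response may accompany the genotype. Of 8 iron-deficiency genes 6 were called higher: BHLH38 at 3.41, BHLH39 at 3.34, BHLH101 at 1.97, OPT3 at 1.09, FRO3 at 0.72 and PYE at 0.52. NAS4 and BTS were not called. FER1, which stores iron, was lower at -1.80. Of the other iron-storage genes listed, FER3 was not called, at 0.12, and FER4 was not measured. All these calls ended with slide as a fixed block, where BHLH38 came to 1.79, BHLH39 to 1.72, BHLH101 to 1.43, OPT3 to 0.93, FRO3 to 0.45, PYE to 0.50 and FER1 to -1.96, with 3 residual degrees of freedom. Without replicate 2 of the watered mutant BHLH38, BHLH39 and BHLH101 lost their calls, at 2.69, 2.70 and 1.61, and without replicate 3 BHLH38, BHLH39 and OPT3 did, at 3.32, 3.17 and 1.02. BHLH38 was also not called without replicate 1 of the watered wild type, at 2.39. PYE lost its call without any 1 array except replicate 2 of the watered wild type and replicates 2 and 3 of the droughted mutant, with values from 0.34 to 0.58. The list had a median of 0.91 over all arrays and 0.90 within the shared slide. BHLH100, BHLH38 and BHLH39 were above background on 2 of 3 watered wild-type arrays, so their folds are imprecise, and iron content was not analysed here.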
